A study of Mus musculus with 28 samples.

How the data were processed

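The series holds 28 RNA samples of the mouse tumour line MC38, a colon adenocarcinoma line of C57BL/6 origin, and of OT1 T cells, CD8 T cells whose transgenic receptor recognises an ovalbumin peptide. Of these, 19 MC38 libraries have a column in the 2 tables used here, and the 9 libraries of OT1 T cells, with the 3 comparisons planned between them, were not analysed here. The in vitro table has 10 libraries, 2 each of untreated cells and of cells given TNF, IFNG, TNF and IFNG together, or supernatant of a co-culture. The co-culture table has 9 libraries, 3 each of MC38 alone, MC38 cultured with OT1 T cells and an isotype control antibody, and MC38 cultured with OT1 T cells and an antibody against PD1, the inhibitory T cell receptor whose ligand is encoded by Cd274. Treatment with the cytokines or the T cells lasted 6 hours, per the labels. No treatment time is recorded for supernatant, so it may differ.

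Groups were taken from the labels. The third anti-PD1 library has labels in conflict: its title and treatment field call it untreated, whereas its description ties it to the column of MC38 with OT1 T cells and PD1 antibody. It was placed by its description, and every comparison was repeated without it. One library of the isotype group is described with OT2 in place of OT1. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

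Per the labels' protocols, RNA was extracted with a NucleoSpin kit and made into QuantSeq 3' mRNA libraries, which read the 3' end of each transcript, so a value does not grow with transcript length. The submitters' processing notes name FastQC, cutadapt 1.7, HISAT2, featureCounts, Subread and limma, and the builds GRCm38 and mm10, without their order or settings. Whether counting used the strand is not given in the sources used here. The deposited values are log2 CPM, counts scaled to a common total per library. This unit was read from the values: 2 to the power of the values sums to between 993229 and 998505 in each library, close to the fixed total of CPM. Within each table the libraries share the same maximum, and their sorted values differ by at most 0.0235 (in vitro) and 0.0238 (co-culture) in the upper part of the distribution, as quantile normalization by the authors would leave them. The tables were normalized separately, so every test was made within a table. Because the values are normalized, a shift that raises or lowers most transcripts together cannot be seen in them. Of the in vitro gene names, 15 had been turned into dates, with 1 name duplicated; these entries were tested and are not named.

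Raw counts were not used here. Low values fall in tied steps, as whole read counts do, and the number of distinct steps below the median value gives the approximate read count of the median gene. There were 51 to 169 such steps per library in vitro and 54 to 160 in co-culture. Under the assumption that every whole count occurs, this implies 3360000 assigned reads for the second TNF + IFNG library, the lowest in vitro, and 11200000 for the first IFNG library, the highest. In co-culture the third library of MC38 alone was lowest, with 3730000, and the third anti-PD1 library highest, with 11000000. A change between 1 and 3 reads is therefore within counting error, and genes whose control libraries lie on the lowest 3 steps are named as such. The median half-width of the 95% confidence interval of a log2 fold was 0.59 in vitro (0.83 for the interaction) and 0.49 in co-culture.

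All groups of a table were fitted together with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along an intensity trend, on the deposited log2 values. This left 5 residual degrees of freedom plus 3.74 from the prior in vitro, and 6 plus 4.12 in co-culture. A gene was tested if its log2 value was at least 0 in as many libraries as the smallest group, 2 or 3. The filter removed 0 of 12721 genes in vitro and 239 of 12948 in co-culture. A further 1 and 2 genes had the same value in every library and were not tested, which left 12720 and 12707 genes, of which 12165 were tested in both. P-values are 2-sided and were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes carry limma's standard error (SE), and group levels the standard deviation (SD). The interaction contrast asks whether the log2 change with both cytokines differs from the sum of the changes with each.

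The 21 gene lists, the gene-naming rule, the tests, the filter and the alternatives were fixed before the data were examined. Lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. The number of members past the threshold is given over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives. Lists with fewer than 3 tested members were not tested: MHC class II in both tables (1 and 2 members), T cell markers in vitro (1) and myeloid and B cell markers in co-culture (2). The genes named are a fixed panel of 21 genes on NF-kB, interferon, antigen presentation and death receptor signalling, up to 8 genes that rose most and up to 6 that fell most among those past the threshold with a mean at or above the median gene and no overlap between groups, up to 4 called members of each list by size of change, and 6 genes as a measure of T cell RNA. Genes named outside this rule are said to be so, and 1 gene of the panel is not reported here. Calls shared by the tables were compared with Fisher's exact test over the 12165 genes, beside the number expected of independent lists. Genes are not independent replicates, so that comparison is descriptive. Coordinates and gene types are those of the GRCm38 annotation, in which 98.4% of the genes tested in vitro and 98.5% of those in co-culture were found by name.

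The fit was tested on simulated libraries with 200 changed genes, drawn at the tables' means and implied depths with a dispersion of 0.02. The changed genes were taken only from those with a mean well above the filter threshold, so recovery of low genes was not tested. All genes and groups had the same dispersion, whereas the real median SD between replicates was 0.262 with TNF + IFNG and 0.118 with IFNG. The false calls below therefore do not cover unequal spread between groups. For TNF against untreated, 78% of 100 genes changed 2-fold and 100% of those changed 4-fold were recovered, with 8 false calls among 12170 unchanged genes. For TNF + IFNG these values were 78% and 100%, with 18 false calls. For the interaction they were 35% and 97%, with 10 false calls, and for supernatant against TNF + IFNG 81% and 100%, with 25. In co-culture they were 95% and 100%, with 10 false calls, for isotype against MC38 alone, and 100% and 100%, with 8, for anti-PD1 against isotype.

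The alternatives were no filter, a stricter filter at a log2 value of 3.3, values below 0 raised to 0, median scaling, a further quantile normalization, limma without the trend, limma with robust moderation, the replicate number as a block, only the groups compared, a minimum absolute log2 fold of 1, and each replicate left out in turn. For the shared calls, the anti-PD1 co-culture also took the place of the isotype co-culture. Library weights and a co-culture fit to genes also in the in vitro table were added after the data were seen. The alternatives planned for linear values or counts (another pseudocount, count models) were not run, because the tables hold log2 values. Figures were drawn with matplotlib 3.10.9.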

Results

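RNA of the mouse tumour line MC38 was profiled from the 3' end of transcripts in 19 libraries. In the in vitro table, 2 libraries each came from untreated cells and from cells given TNF, IFNG, both cytokines, or supernatant of a co-culture. In the co-culture table, 3 libraries each came from MC38 alone, from MC38 with OT1 T cells and an isotype antibody, and from MC38 with OT1 T cells and an antibody against PD1. Values were deposited as normalized log2 CPM, and the implied depth was 3360000 to 11200000 reads in vitro and 3730000 to 11000000 in co-culture. The tables were normalized separately, so levels in one cannot be set against levels in the other. In vitro folds rest on n = 2 per group and co-culture folds on n = 3, and errors are limma's SE throughout.

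TNF raised genes of the NF-kB pathway, the transcription factor pathway that TNF receptors feed into. Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, rose 10.5-fold (log2 fold change 3.39 ± 0.14, adjusted p = 3.4e-05), from a log2 level of 7.83 ± 0.06 (SD) to 11.23 ± 0.07. Nfkbie, another inhibitor of the family, rose by 3.17 ± 0.27 on the log2 scale (adjusted p = 0.0027). The neutrophil chemokine Cxcl1 and the monocyte chemokine Ccl2 rose by 3.47 ± 0.52 and 3.22 ± 0.43 (adjusted p = 0.0417 and 0.0225). Irf1, an interferon-regulatory transcription factor, rose 5.53-fold (2.47 ± 0.12, adjusted p = 6.21e-05). Nfkbia lies on chromosome 12 (55489410 to 55492647, minus strand, GRCm38) and Irf1 on chromosome 11 (53770014 to 53778374, plus strand). Cxcl1 lies on chromosome 5 (90891241 to 90893115, plus strand) and Ccl2 on chromosome 11 (82035571 to 82037453, plus strand).

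By groups, 8 of 26 NF-kB targets rose with TNF over all genes and 20 adjusted over the list alone. Their median log2 fold was 1.46 (camera adjusted p = 2.69e-35). Of 9 chemokine genes 4 rose, among them Cxcl10 (2.18 ± 0.26) and Ccl5 (1.33 ± 0.16). Adjusted over the list alone, 6 rose and 1 fell (median 2.01, adjusted p = 1.93e-11). In the interferon response list 3 of 33 members rose (7 adjusted over the list alone), namely Irf1, Cxcl10 and Parp14. Its median was 0.39 (adjusted p = 5.15e-07, and adjusted p = 0.0527 with an estimated correlation). None of the 14 interferon-induced GTPases passed over all genes, and 5 rose and 1 fell adjusted over the list alone. That list had adjusted p = 0.00022, and adjusted p = 0.174 with an estimated correlation. In the TNF and death receptor pathway none of 30 genes passed over all genes, and 3 rose adjusted over the list alone. This list had adjusted p = 0.00115, and adjusted p = 0.0527 with an estimated correlation. Fas, a death receptor, stood at 2.39 ± 0.40 (adjusted p = 0.063), Icam1, with both control libraries at the detection floor, at 3.46 ± 0.96 (adjusted p = 0.422) and Cd274, the ligand of PD1, at 0.43 ± 0.38 (adjusted p = 0.888). Slfn2 (2.89 ± 0.21) and the vesicle fusion gene Stx11 (2.32 ± 0.17) also rose. The 2 genes that fell were Id2, an inhibitor of helix-loop-helix factors (−1.48 ± 0.17), and Ier5l (−1.84 ± 0.19).

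In all, 33 genes rose and 2 fell with TNF among 12720 tested. The total of 35 was 18 without the first and 11 without the second untreated library, and 20 and 14 without the first and the second TNF library. It was 18 without the intensity trend, 61 with only the compared groups fitted, and 72 with library weights. Without an untreated or a TNF library, Cxcl1, Ccl2, Ccl5, Cxcl10 and Id2 no longer passed (adjusted p up to 0.276, 0.194, 0.173, 0.144 and 0.123). Cxcl1 was also lost without either IFNG library (0.0878), Ier5l without the second untreated or the second TNF library (0.0851), and Parp14 without the second untreated library (0.0886).

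**Figure D1:**
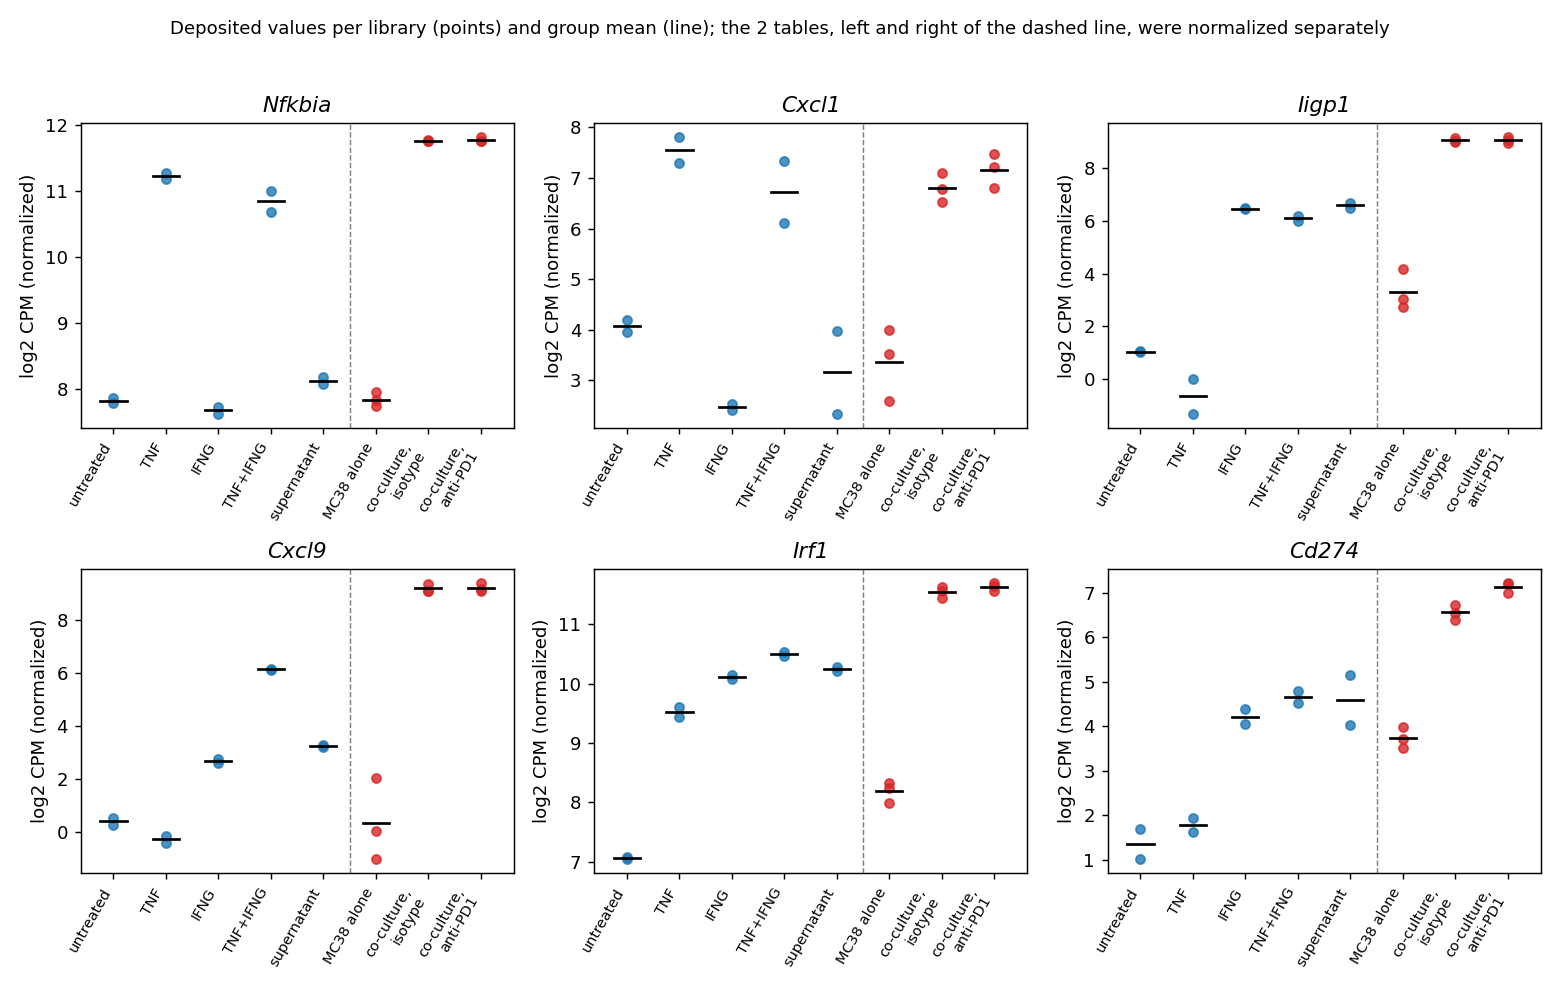
Normalized log2 CPM of 6 genes in each library (points) with the group mean (line), for the 5 in vitro groups (blue, n = 2) and the 3 co-culture groups (red, n = 3), whose tables were normalized separately. Nfkbia was high with TNF, with both cytokines and in co-culture, Iigp1 with IFNG, both cytokines, supernatant and co-culture, and Cxcl9 rose from 0.40 in untreated cells to 2.66 with IFNG and 6.13 with both cytokines.

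IFNG raised genes of the interferon response. Iigp1, a GTPase that attacks the vacuoles of intracellular pathogens, rose 42.8-fold (5.42 ± 0.36, adjusted p = 0.00019), and Irf1 rose 8.32-fold (3.06 ± 0.12, adjusted p = 1.49e-05). Cxcl9 and Cxcl10, chemokines that attract T cells, rose by 2.26 ± 0.23 and 2.66 ± 0.26 (adjusted p = 0.00208 and 0.00198), and Cd274 rose 7.30-fold (2.87 ± 0.38, adjusted p = 0.0136). Iigp1 lies on chromosome 18 (60376027 to 60392634, plus strand), Cd274 on chromosome 19 (29367455 to 29388095, plus strand), and Cxcl9 and Cxcl10 are neighbours on the minus strand of chromosome 5 (92321347 to 92328079 and 92346638 to 92348889).

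Among interferon-induced GTPases, 11 of 14 rose with IFNG (13 adjusted over the list alone, median 3.24, adjusted p = 3.93e-36). Tgtp1 and Tgtp2 (5.32 ± 0.24 and 5.14 ± 0.24) are near-identical copies. Irgm2 and Igtp (4.95 ± 0.44 and 4.62 ± 0.19) overlap on the plus strand of chromosome 11 (58199618 to 58222782 and 58199556 to 58207591). All 4 are uncertain as single genes, since counting can have split their reads. In the interferon response list 10 of 33 rose (24 adjusted over the list alone, median 1.28, adjusted p = 4.06e-32), among them Parp14 (2.99 ± 0.22) and Stat2 (2.65 ± 0.18). Of 24 genes of the MHC class I pathway, which shows peptides to CD8 T cells, 2 rose (5 adjusted over the list alone, median 0.09, adjusted p = 0.213). These were the peptide transporter Tap1 (2.11 ± 0.16, adjusted p = 0.000503) and the class I transactivator Nlrc5 (2.30 ± 0.37, adjusted p = 0.0477). The heavy chain H2-K1 stood at 0.08 ± 0.24 and the light chain B2m at −0.13 ± 0.15. No NF-kB target passed over all genes (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.696), and Nfkbia stood at −0.15 ± 0.14. Of 9 chemokines 2 rose over all genes (3 rose and 3 fell adjusted over the list alone, adjusted p = 0.465).

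Of 12720 genes, 45 rose with IFNG and none fell, and 1361 had an unadjusted p under 0.05 in limma. The total was 29 without the first IFNG library and 297 with library weights. With only the compared groups fitted it was 480, of which 116 rose and 364 fell. Cd274 no longer passed without the first untreated library or either IFNG library (adjusted p = 0.113, 0.0925 and 0.128), and Nlrc5 was lost without any one library other than the first untreated one (adjusted p up to 0.309).

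Cells given both cytokines carried both programmes. Cxcl9 rose 52.9-fold (5.73 ± 0.23, adjusted p = 1.09e-05), Cxcl10 rose 19.8-fold (4.31 ± 0.26, adjusted p = 6.63e-05). Cxcl11, a further T cell chemokine that the annotation lists as a polymorphic pseudogene, rose by 6.88 ± 0.48 (adjusted p = 0.000169), with 1 control library at the detection floor. Nfkbia and Irf1 rose by 3.02 ± 0.14 and 3.44 ± 0.12, and Cd274 by 3.31 ± 0.38 (adjusted p = 0.00296). Fas rose 5.59-fold (2.48 ± 0.40, adjusted p = 0.0146). Tnfsf10, which encodes the death ligand TRAIL, rose by 3.65 ± 0.74 (adjusted p = 0.0277), with both control libraries at the detection floor, and its fold was 4.39 and 2.91 without the first and the second of them. Cxcl11 lies beside Cxcl10 on chromosome 5 (92359544 to 92365485, minus strand) and Fas on chromosome 19 (34290666 to 34327772, plus strand).

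The GTPases rose in 13 of 14 cases (14 adjusted over the list alone, median 3.60, adjusted p = 9.63e-21) and the interferon response genes in 18 of 33 (22 adjusted over the list alone, median 1.23, adjusted p = 2.21e-16). Of the NF-kB targets 17 of 26 rose, including Nfkbie (3.74 ± 0.27), and 20 rose and 1 fell adjusted over the list alone (median 1.57, adjusted p = 3.41e-12). Of the chemokines 7 of 9 rose (7 adjusted over the list alone, median 2.04, adjusted p = 7.26e-09). In the death receptor pathway 5 of 30 genes rose, among them the apoptosis inhibitor Birc3 (1.54 ± 0.26), and 1 fell (11 up and 2 down adjusted over the list alone). Its median was 0.45 (adjusted p = 0.00555, and adjusted p = 0.0582 with an estimated correlation). Cd274 and Cd47, a signal against phagocytosis (0.88 ± 0.16), were the 2 of 7 checkpoint ligands that rose (3 adjusted over the list alone). That list had a median of 0.88 (adjusted p = 0.0217, and adjusted p = 0.112 with an estimated correlation), and was lost without the first TNF + IFNG library (0.113). In the MHC class I list 6 of 24 rose (8 up and 4 down adjusted over the list alone, median 0.07, adjusted p = 0.236), among them Tap1 (2.18 ± 0.16) and the tapasin-like gene Tapbpl (1.85 ± 0.19). H2-K1 stood at −0.45 ± 0.24 (adjusted p = 0.232) and B2m at −0.41 ± 0.15 (adjusted p = 0.0998). Of the pyroptosis genes, Casp4 (1.45 ± 0.28) and the pore protein gene Gsdmd (1.27 ± 0.23) rose, 2 of 5 over all genes and also adjusted over the list alone (adjusted p = 0.236). Gnb2, a G protein subunit, was among the genes that fell (−2.43 ± 0.37, adjusted p = 0.0118).

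In total 607 genes rose and 540 fell, of which 335 and 288 changed at least 2-fold. This total of 1147 was 121 and 88 without the first and the second untreated library, 546 and 550 without the first and the second TNF library, 267 and 272 without the first and the second IFNG library, 307 without the second TNF + IFNG library, and 2155 and 2152 without the first and the second supernatant library. It was 467 without the trend, 594 with the replicate number as a block, 656 with library weights and 145 with only the compared groups fitted. Without the first or the second untreated library Fas, Birc3, Tnfsf10, Cd47, Casp4 and Gsdmd no longer passed (adjusted p up to 0.0837, 0.133, 0.170, 0.126, 0.162 and 0.136), nor did Gnb2 without the second (0.105). All of these except Casp4 and Gnb2 were also lost without the second TNF + IFNG library, Tnfsf10 without the first, and Tnfsf10, Casp4 and Gsdmd without either IFNG library.

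The test of whether the cytokines acted other than additively on the log2 scale singled out Cxcl9 and Irf1. Cxcl9 stood at a log2 level of 0.40 ± 0.17 (SD, n = 2) in untreated cells, −0.28 ± 0.17 with TNF, 2.66 ± 0.11 with IFNG and 6.13 ± 0.03 with both, which is 4.15 ± 0.32 above the sum of the single effects (adjusted p = 0.00492). Irf1 stood at 7.06 ± 0.02, 9.52 ± 0.11, 10.11 ± 0.05 and 10.50 ± 0.04, which is 2.08 ± 0.17 below that sum (interaction −2.08, adjusted p = 0.00492). No other gene passed, and 500 genes had an unadjusted p under 0.05 in limma. The interferon response list lay below additivity, with 1 member up and 1 down over all genes, and 1 up and 4 down adjusted over the list alone. Its median was −0.35 (adjusted p = 0.0106, and adjusted p = 0.495 with an estimated correlation). The chemokines lay above it, with 1 member up over all genes and adjusted over the list alone. Their median was 0.54 (adjusted p = 0.0106, and adjusted p = 0.303 with an estimated correlation). The total of 2 was 0 without the first untreated or the first IFNG library, where both genes were lost, and 4, 4, 9 and 4 without the second untreated, the second TNF, the first TNF + IFNG and the second TNF + IFNG library. It was 1 with the stricter filter, which lost Cxcl9 (adjusted p = 0.0581), and 1 without the trend, which lost Irf1 (0.0883). Irf1 was also lost without the second IFNG library (0.052). The interferon list was lost without the first untreated or the second TNF + IFNG library, and the chemokine list without the latter.

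Supernatant of the co-culture raised interferon genes to a similar extent as IFNG did. Iigp1 rose by 5.55 ± 0.36 and Irf1 by 3.18 ± 0.12. Among chemokines and checkpoint ligands, Cxcl10 rose by 3.34 ± 0.26 (adjusted p = 0.000442), Cxcl11 by 4.61 ± 0.48 (adjusted p = 0.00243) and Cd274 by 3.23 ± 0.38 (adjusted p = 0.00509). Socs1, a feedback inhibitor of cytokine receptors, rose by 2.41 ± 0.32 (adjusted p = 0.012). By contrast, Nfkbia stood at 0.30 ± 0.14 (adjusted p = 0.864), Cxcl1 at −0.93 ± 0.52 (adjusted p = 0.864), Ccl2 at −0.16 ± 0.43 and Fas at 0.39 ± 0.40, none of which passed.

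Interferon response genes rose in 14 of 33 cases with supernatant (26 adjusted over the list alone, adjusted p = 2.69e-51) and GTPases in 11 of 14 (13 adjusted over the list alone, median 3.49, adjusted p = 9.41e-51). Of the chemokines, Cxcl9, Cxcl10 and Cxcl11 rose (3 of 9 over all genes and adjusted over the list alone, median 0.53, adjusted p = 7.15e-05). None of the 26 NF-kB targets passed over all genes (2 rose adjusted over the list alone, median 0.16, adjusted p = 0.0241, and adjusted p = 0.082 with an estimated correlation). Tap1 (2.11 ± 0.16) and Nlrc5 (2.38 ± 0.37) were the 2 MHC class I genes that rose of 24 (5 adjusted over the list alone, median 0.09, adjusted p = 0.00198, and adjusted p = 0.0558 with an estimated correlation). Of the checkpoint ligands 1 of 7 rose (adjusted p = 0.013, and adjusted p = 0.082 with an estimated correlation). Neither the death receptor pathway nor the pyroptosis genes had a member past the threshold over all genes. Adjusted over the list alone, 3 of 30 and 2 of 5 rose (adjusted p = 0.00352 and 0.000898, and adjusted p = 0.0558 and 0.082 with an estimated correlation).

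With supernatant 57 genes rose and none fell among 12720, where 652 had an unadjusted p under 0.05 in limma, and 37 passed with only the compared groups fitted. Cd274 was lost without the first untreated library (adjusted p = 0.0507), Socs1 without either untreated or the first supernatant library (up to 0.123), and Nlrc5 without any one library other than the first untreated one (up to 0.217). The NF-kB list was lost without the first untreated or the first supernatant library (adjusted p up to 0.548), the MHC class I and death receptor lists without the first supernatant library (0.457 and 0.0582), and the checkpoint list without the second untreated or the second supernatant library (up to 0.0654).

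Set directly against TNF + IFNG, supernatant gave lower NF-kB targets and chemokines. The time with supernatant is not recorded, so the treatments may differ in duration as well. Nfkbia was lower by 2.72 on the log2 scale (−2.72 ± 0.14, adjusted p = 0.000231), Nfkbie by −2.88 ± 0.27 (adjusted p = 0.00593), and Ier3, an early NF-kB target, by −2.05 ± 0.14 (adjusted p = 0.00108). Cxcl9 was lower (−2.89 ± 0.23, adjusted p = 0.00247), as were Ccl5 (−1.88 ± 0.16) and Cxcl1 (−3.57 ± 0.52, adjusted p = 0.0475). Of the NF-kB targets 6 of 26 were lower (15 adjusted over the list alone, median −1.11, adjusted p = 8.76e-15) and of the chemokines 3 of 9 (7 adjusted over the list alone, median −1.82, adjusted p = 2.61e-09). The interferon response list (median 0.25, 1 of 33 lower, 2 adjusted over the list alone, adjusted p = 0.845) and the GTPases (median −0.27, none past the threshold over all genes, 1 lower adjusted over the list alone, adjusted p = 0.421) did not pass. Il2, a T cell cytokine gene read in libraries without T cells and therefore uncertain, was lower (−3.78 ± 0.36). It was the 1 member of the T cell effector list past the threshold (2 adjusted over the list alone). That list had adjusted p = 0.0108, and adjusted p = 0.152 with an estimated correlation, and it was lost without the first TNF + IFNG library (0.0575). Ier5l (1.77 ± 0.19) was higher with supernatant.

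This comparison gave 8 higher and 22 lower genes. The total of 30 was 13 without either untreated library, 12 without either TNF library, 12 and 13 without the first and the second IFNG library, 266 and 19 without the first and the second TNF + IFNG library, and 18 and 486 without the first and the second supernatant library. It was 57 with robust moderation, 16 with the replicate number as a block, 6 with library weights and 4 with only the compared groups fitted. Cxcl1 was lost without any one untreated, TNF or IFNG library or the second TNF + IFNG library (adjusted p up to 0.190), and its log2 fold lay between −4.39 and −2.76 without a TNF + IFNG or supernatant library.

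Co-culture with OT1 T cells under isotype antibody raised interferon genes, NF-kB targets and chemokines together. Cxcl9 rose 453-fold (8.82 ± 0.58, adjusted p = 4.68e-06), Cxcl10 68.6-fold (6.10 ± 0.20, adjusted p = 4.52e-08), Cxcl11 by 7.20 ± 0.39 and Ccl2 32.4-fold (5.02 ± 0.11, adjusted p = 5.83e-09). Nfkbia rose from a log2 level of 7.85 ± 0.10 (SD, n = 3) to 11.76 ± 0.01, a fold of 15.1 (adjusted p = 6.31e-09), and Irf1 by 3.35 ± 0.11. The log2 fold of Cxcl9 was 8.14 and 9.67 without the first and the third library of MC38 alone. Ubd, a ubiquitin-like modifier induced by TNF and IFNG, rose by 6.88 ± 0.23, and Cd274 rose 7.06-fold (2.82 ± 0.15, adjusted p = 9.1e-07). Genes of the response to low oxygen fell, among them Bnip3, a mitophagy receptor (−2.05 ± 0.12, adjusted p = 2.24e-06), and Ankrd37 (−3.64 ± 0.39, adjusted p = 0.000149).

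Interferon response genes rose in 32 of 34 cases (34 adjusted over the list alone, median 1.75, adjusted p = 2.02e-37) and GTPases in 14 of 15 (14 adjusted over the list alone, median 3.97, adjusted p = 2.22e-26), with Iigp1 (5.73 ± 0.29) and Gbp4 (5.61 ± 0.14) as examples. Gbp2b (5.73 ± 0.29) and Gm4841 (6.88 ± 0.33), interferon-induced GTPase genes outside the list, have close copies and are uncertain. Of the NF-kB targets 22 of 26 rose (23 adjusted over the list alone, median 1.76, adjusted p = 1.6e-29). All 11 chemokines rose, also adjusted over the list alone (median 4.53, adjusted p = 1.05e-21), including Cxcl1 (3.43 ± 0.32) and Ccl7 (4.05 ± 0.25). Ccl3 and Ccl4 of this list are also in the list of T cell effector genes, so T cell RNA can add to their rise. Ccl3 had all 3 controls at the detection floor. The MHC class I list had 15 of 24 members up (17 adjusted over the list alone, median 0.79, adjusted p = 2.86e-11). Tap1 rose by 2.86 ± 0.19 and Nlrc5 by 2.81 ± 0.25, with H2-K1 at 0.39 ± 0.10 (adjusted p = 0.0252). In the death receptor pathway 13 of 30 rose (14 adjusted over the list alone, median 0.30, adjusted p = 2.36e-06). Fas stood at 4.09 ± 0.43, Tnfsf10, with 1 of 3 controls at the detection floor, at 4.18 ± 0.51 (3.43 without the third library of MC38 alone), the nucleic acid sensor Zbp1 at 3.44 ± 0.22 and the caspase-8 inhibitor Cflar at 1.15 ± 0.17. Checkpoint ligands rose in 4 of 8 cases (4 adjusted over the list alone, median 1.22, adjusted p = 1.32e-05). These were Cd274, Lgals9 (1.47 ± 0.24), Cd47 (1.31 ± 0.11) and Nos2, the inducible nitric oxide synthase (3.82 ± 0.36, 1 of 3 controls at the detection floor). Pyroptosis genes rose in 4 of 6 cases (5 adjusted over the list alone, median 1.40, adjusted p = 0.000333), with Casp4 at 2.55 ± 0.22 and Casp1 at 1.36 ± 0.22. Hypoxia and glycolysis genes fell in 9 of 19 cases and none rose (12 fell adjusted over the list alone, median −0.34, adjusted p = 7.88e-08). Among them were the oxygen sensor Egln3 (−1.66 ± 0.18) and the glucose transporter Slc2a1 (−1.20 ± 0.11). Ddit4, an mTOR inhibitor induced by stress, fell by 2.58 on the log2 scale (−2.58 ± 0.21, adjusted p = 2.8e-05). Bnip3 lies on chromosome 7 (138890836 to 138909519, minus strand), Ankrd37 on chromosome 8 (45996902 to 46005707, minus strand) and Ddit4 on chromosome 10 (59949669 to 59951834, minus strand).

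T cell genes were measured in these libraries too. Of 21 T cell effector genes 15 rose (18 adjusted over the list alone). Their median was 3.42 (adjusted p = 2.65e-13, and adjusted p = 0.0518 with an estimated correlation). Among them were Ifng (7.29 ± 0.87, adjusted p = 0.000341) and the chemokine gene Xcl1 (6.30 ± 0.88), both with 2 of 3 controls at the detection floor. Of 15 T cell markers 5 rose (11 adjusted over the list alone, median 2.57, adjusted p = 1.18e-05, and adjusted p = 0.245 with an estimated correlation). The third library of MC38 alone held T cell markers at a summed 50.0 CPM, against 4.20 and 4.75 in the other controls and 44.2 to 56.5 in the co-cultures, and effector genes at 69.2 CPM against 47.1 and 26.7 in the other controls and 328 to 405 in the co-cultures. Much of the effector sum in the other controls came from Tnfrsf9 (log2 4.31 and 4.09) and, in the first, Il2 (4.16). The median log2 value of the effector genes was −2.58 and −2.66 in the other controls and 2.90 to 3.34 in the co-cultures, against 0.69 in the third library of MC38 alone. Without that library the marker list had 13 members up (median 3.71) and the effector list 18 (median 4.37). The log2 folds of Ifng, Xcl1 and Gzmb were then 8.62, 7.67 and 6.58. They were 6.37 for Ifng without the second library of MC38 alone, 5.64 and 5.60 for Xcl1 without the first and the second, and 3.60 for Gzmb without the first. Gzmb, a cytotoxic granule protease (4.81 ± 1.16, adjusted p = 0.0215) with 2 of 3 controls at the detection floor, was lost without the first or the second library of MC38 alone or any isotype library (adjusted p up to 0.0704). Tnf (2.87 ± 0.63, adjusted p = 0.0135), with all controls at the detection floor, was lost without the second or the third isotype library (0.0525 and 0.0766).

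Under isotype antibody 971 genes rose and 790 fell among 12707, of which 581 and 219 changed at least 2-fold. The total of 1761 was 1071 without the first isotype library, 1006 without the third, and 2223 without the third library of MC38 alone. H2-K1 was lost without any one isotype library (adjusted p up to 0.0954).

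**Figure D2:**
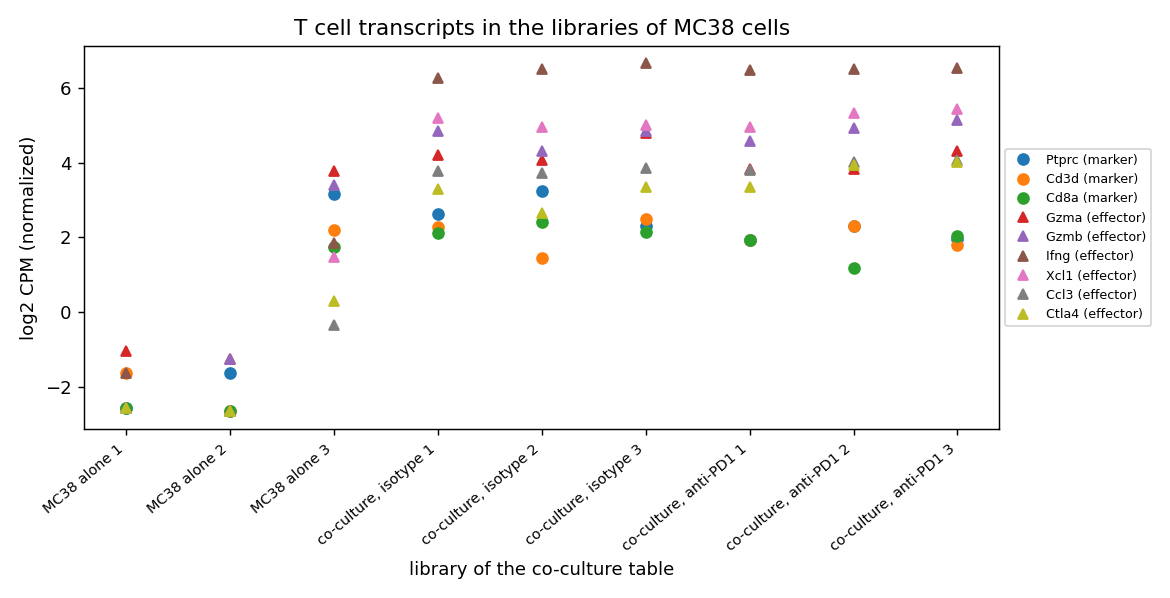
Normalized log2 CPM of 3 T cell markers (circles) and 6 T cell effector genes (triangles) in each of the 9 co-culture libraries. The third library of MC38 alone holds the markers at co-culture levels, with Ifng at 1.85 against 6.27 to 6.66 in the co-cultures.

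With the anti-PD1 antibody the co-culture changed the same gene groups against MC38 alone. Cxcl9 rose by 8.86 ± 0.58 (adjusted p = 4.57e-06; 8.17 and 9.70 without the first and the third library of MC38 alone), Ccl2 by 5.42 ± 0.11 (adjusted p = 2.67e-09), Nfkbia by 3.93 ± 0.09 (adjusted p = 7.42e-09) and Cd274 10.5-fold (3.40 ± 0.15, adjusted p = 2.7e-07). Lif, a cytokine of the interleukin-6 family, rose by 4.45 ± 0.25 and the peptide transporter gene Tap2 by 2.70 ± 0.24. Bnip3 fell (−1.75 ± 0.12, adjusted p = 6.54e-06), as did Slc5a3, an inositol transporter (−2.24 ± 0.13), and Zmiz1 (−1.95 ± 0.16). The mitochondrial pseudogenes Gm28437 (−3.26 ± 0.78), Gm10925 (−3.10 ± 0.82) and Gm28661 (−3.10 ± 0.65) on chromosome 1 resemble mitochondrial transcripts and are uncertain. Their folds were −2.54, −2.33 and −2.25 without the second anti-PD1 library and −4.41, −4.26 and −3.81 without the third.

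By lists, 32 of 34 interferon response genes rose (32 adjusted over the list alone, median 1.75, adjusted p = 4.4e-34), as did 22 of 26 NF-kB targets (25 adjusted over the list alone, median 2.10, adjusted p = 1.12e-29). So did 14 of 15 GTPases (14 adjusted over the list alone, median 3.77, adjusted p = 2.08e-25) and all 11 chemokines (11 adjusted over the list alone, median 4.87, adjusted p = 6.71e-21). Of these chemokines, Ccl3 and Ccl4 are also in the list of T cell effector genes. The MHC class I list had 14 of 24 up (19 up and 2 down adjusted over the list alone, median 0.80, adjusted p = 5.34e-11) and the death receptor pathway 13 of 30 (14 adjusted over the list alone, median 0.44, adjusted p = 3.34e-07). Of the checkpoint ligands 4 of 8 rose (4 adjusted over the list alone, median 1.23, adjusted p = 3.8e-05), and of the pyroptosis genes 3 of 6 (5 adjusted over the list alone, median 1.36, adjusted p = 0.000651). Hypoxia and glycolysis genes fell in 10 of 19 cases (12 adjusted over the list alone, median −0.39, adjusted p = 6.05e-07). T cell effector genes rose in 15 of 21 cases (17 adjusted over the list alone), with adjusted p = 1.1e-12, and adjusted p = 0.0525 with an estimated correlation. T cell markers rose in 3 of 15 cases (8 adjusted over the list alone), with adjusted p = 3.54e-05, and adjusted p = 0.259 with an estimated correlation. Without the third library of MC38 alone, which held marker transcripts at 50.0 CPM, 18 and 14 rose (medians 4.55 and 3.36). In all, 1070 genes rose and 980 fell, of which 596 and 263 changed at least 2-fold. The total of 2050 was 1314, 1226 and 1228 without the first, the second and the third anti-PD1 library, of which the third has labels in conflict. It was 2571 without the third library of MC38 alone, and 1251 with only the compared groups fitted. Gm10925 was lost without any one library of MC38 alone or the first or the second anti-PD1 library (adjusted p up to 0.0974), and Gm28437 without the first of MC38 alone or the first or the second anti-PD1 library (up to 0.0721).

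No gene differed between the anti-PD1 and the isotype co-culture in limma, in which 347 genes (2.73% of those tested) had an unadjusted p under 0.05. The log2 folds of Ifng (0.03, 95% confidence interval −1.91 to 1.96), Gzmb (0.21, −2.37 to 2.79) and Cd8a (−0.50, −2.68 to 1.67) had wide intervals in this fit, which includes the spread of MC38 alone. With only the co-culture groups fitted the intervals were −0.23 to 0.28 for Ifng, −0.22 to 0.64 for Gzmb, −1.12 to 0.12 for Cd8a and −1.66 to 0.59 for Tnf. That of the leukocyte gene Ptprc (−0.67) was −1.27 to −0.06, which leaves out 0 before adjustment (limma unadjusted p = 0.0338, adjusted p = 0.842). The NF-kB list was higher with anti-PD1 (median 0.09, adjusted p = 0.0241, and adjusted p = 0.215 with an estimated correlation), with none of its 26 members past the threshold over all genes or adjusted over the list alone. Adjusted over the list alone, 1 member each passed for the MHC class I list (Tap2, 1.01 ± 0.24, adjusted p = 0.0449), the checkpoint ligands (Cd274, 0.58 ± 0.15, 0.0244), the chemokines (Ccl2, 0.40 ± 0.11, 0.0455) and the unfolded protein response (0.0455). In this comparison Tap2 is named outside the naming rule. The call of the NF-kB list was lost without the first or the second library of either co-culture group, and the count of 0 became 1 with robust moderation, with library weights, and without any one isotype library or the first or the second anti-PD1 library.

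Calls were shared between the tables, which have no library in common. Of 33 genes raised by TNF, 32 were also raised in the isotype co-culture (2.38 expected of independent lists, Fisher's exact test, adjusted p = 1.13e-35), as were 45 of 45 raised by IFNG (3.24 expected, adjusted p = 4.21e-52), 54 of 57 raised by supernatant (4.10 expected, adjusted p = 5.36e-58) and 241 of 597 raised by TNF + IFNG (43.0 expected, adjusted p = 7.09e-125). Of 538 genes lowered by TNF + IFNG, 100 fell in co-culture (34.5 expected, adjusted p = 9.41e-23). Among 28 genes raised by TNF and not called with IFNG, the median log2 fold was 1.88 with TNF, 1.98 with both cytokines, 0.30 with supernatant and 2.04 in the isotype co-culture, where 27 rose, against 1 with supernatant. The 40 genes raised by IFNG and not called with TNF had medians of 2.82 with IFNG, 3.02 with both, 3.00 with supernatant and 3.51 in co-culture. Whether these classes differ in their response to a cytokine was not tested beyond the interaction. For TNF the shared count was 11 and 8 without the first and the second untreated library, 12 and 9 without the first and the second TNF library, and 21 without either IFNG library. For IFNG it was 28 and 29 without the first and the second IFNG library. For TNF + IFNG it was 82 and 68 without the first and the second untreated library, 128 without either IFNG library and 116 without the second TNF + IFNG library. The shared count was also 14 (TNF) without the trend, 59 (TNF) and 122 (IFNG) with library weights, and 80 (IFNG) and 76 (TNF + IFNG) with only the compared groups fitted.

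**Figure D3:**
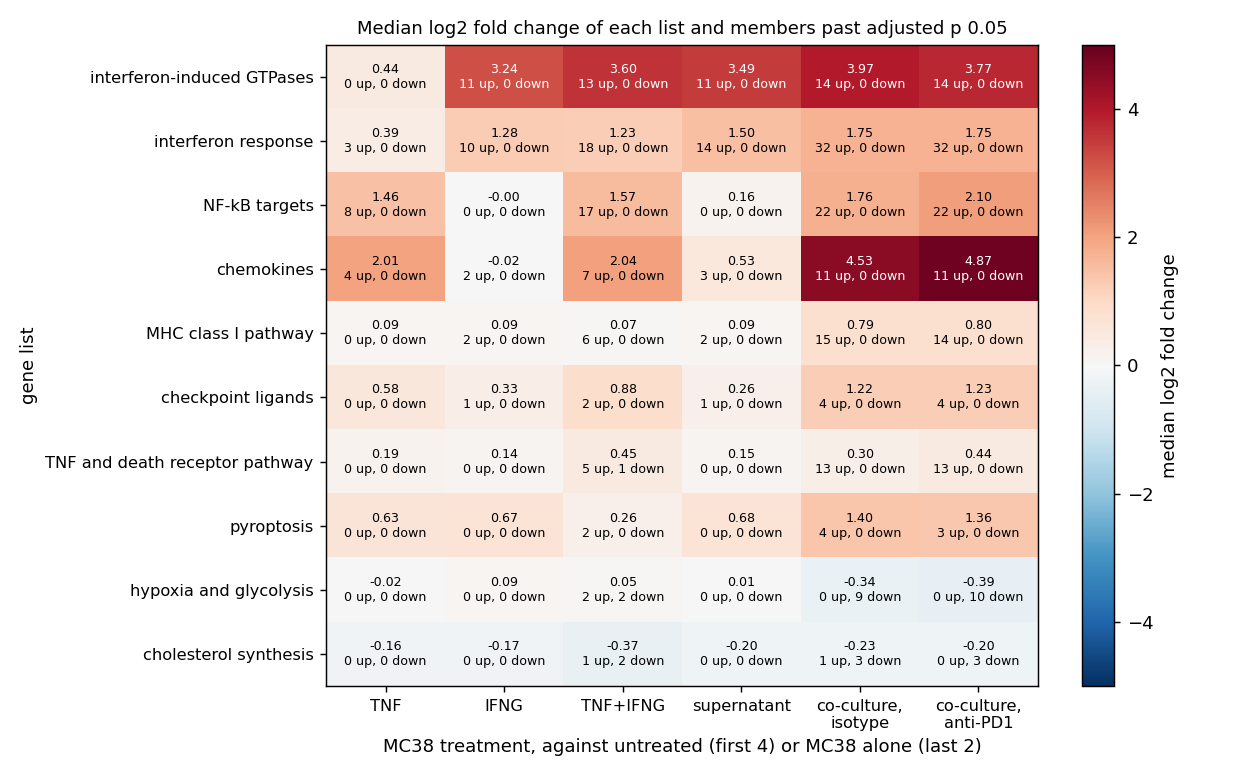
Median log2 fold change of 10 gene lists in 6 comparisons (colour and upper number) with the members past an adjusted p of 0.05 over all genes. The chemokine list had 9 tested members in vitro and 11 in co-culture, where they include the T cell effector genes Ccl3 and Ccl4. GTPase medians lie between 3.24 and 3.97 in the 5 comparisons other than TNF, and NF-kB medians at 1.46, 1.57, 1.76 and 2.10 with TNF, both cytokines and the 2 co-cultures, against 0.16 with supernatant.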

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

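The interaction of the cytokines behind both results of this part was a planned test, and no test here was chosen after the results were seen. Of 12720 genes, 2 had an effect of TNF that differed between cells with and without IFNG, which is why they are listed here.

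For Cxcl9, which encodes a chemokine for activated T cells, the effect of TNF was 4.15 ± 0.32 (log2, SE) larger with IFNG than without it (limma adjusted p = 0.00492). Its mean log2 level was 0.40 in untreated cells, −0.28 with TNF, 2.66 with IFNG and 6.13 with both, with 2 libraries per group. For Irf1, a transcription factor induced by interferon, the effect of TNF was smaller with IFNG (−2.08 ± 0.17, adjusted p = 0.00492), with levels of 7.06, 9.52, 10.11 and 10.50 in the same order. Both calls were lost without the first untreated library (adjusted p = 0.0514) and without the first IFNG library (0.0607), and that of Irf1 also without the second IFNG library (0.052). The call of Cxcl9 was lost with the stricter filter (adjusted p = 0.0581) and that of Irf1 in limma without the trend (0.0883), and the cause was not tested.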

How the results depend on the processing

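The settings of library weights and a co-culture fit to genes also in the in vitro table were chosen after the results were seen, and all others were planned. Of 301 calls of named genes 171 passed under every alternative that tested them, as did 35 of 72 list calls, and none reversed. The stricter filter tested 269 of these gene calls and 66 of the list calls, and the fit to shared genes 150 gene calls. All 37 list calls that were lost were lost with an estimated correlation, and 8 of them also with fry. No count of genes moved by over 1.5 times with values below 0 raised to 0, median scaling, a further quantile normalization, no filter, the co-culture fit to shared genes or the anti-PD1 co-culture in place of the isotype co-culture. The filter removed 0 genes in vitro, so leaving it out says nothing there. Another pseudocount and count models were planned and not run, because the tables hold log2 values.

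The stricter filter gave 1 gene for the interaction. Without the trend the counts were 18 for TNF, 467 for TNF + IFNG, 1 for the interaction and 14 for genes shared by TNF and co-culture. Robust moderation gave 57 for supernatant against TNF + IFNG and 1 for anti-PD1 against isotype. Library weights gave 72 for TNF, 297 for IFNG, 656 for TNF + IFNG, 6 for supernatant against TNF + IFNG, 1 for anti-PD1 against isotype, and 59 and 122 shared genes for TNF and IFNG. With only the compared groups fitted the counts were 61 for TNF, 480 for IFNG, 145 for TNF + IFNG, 37 for supernatant, 4 for supernatant against TNF + IFNG, 1251 for anti-PD1, and 80 and 76 shared genes for IFNG and TNF + IFNG. A fold of at least 2 left, by construction, fewer genes: 623 for TNF + IFNG, 800 for isotype and 859 for anti-PD1. For the settings other than the minimum fold the cause was not tested.

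The replicate number as a block gave 594 genes for TNF + IFNG and 16 for supernatant against TNF + IFNG, and no other count moved by over 1.5 times. Deviations of libraries with the same number had a mean correlation of −0.0275 in vitro (0 of 20 pairs over 0.1) and 0.0167 in co-culture (1 of 9). Shared replicate numbers thus give no sign of pairing. With 2 libraries per group the in vitro deviations mirror each other, so those 20 pairs are not independent. The first TNF + IFNG library varied with the second supernatant library (r = 0.287), and with the first in the opposite direction (−0.287). These groups therefore share variation across the numbers, whose cause was not tested.

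With 1 library left out at a time there were 11 to 41 genes for TNF, 29 to 50 for IFNG, 88 to 2155 for TNF + IFNG, 46 to 65 for supernatant, 0 to 9 for the interaction, 12 to 486 for supernatant against TNF + IFNG, 1006 to 2223 for isotype, 1226 to 2571 for anti-PD1, and 0 to 1 for anti-PD1 against isotype. Shared genes numbered 8 to 34 for TNF, 28 to 45 for IFNG, 68 to 277 for TNF + IFNG and 39 to 56 for supernatant. The lowest count for TNF and TNF + IFNG came without the second untreated library, and the highest for both co-cultures without the third library of MC38 alone. The cause was not tested. An in vitro group reduced to 1 library was assumed to vary like the other groups. Depth limits genes near the detection floor most, since the shallowest libraries, the second of TNF + IFNG and the third of MC38 alone, had 51 and 54 count steps below the median gene.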

Other observations

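The tests of the 3 patterns below were chosen after the results were seen, except that of resting T cell genes, as were the comparisons of supernatant with each single cytokine, whereas the list tests and the splits of libraries were planned. In co-culture with isotype antibody, 9 of 13 immediate early and stress genes changed, 7 up and 2 down (7 and 3 adjusted over the list alone), with a median log2 change of 1.13 (camera adjusted p = 0.000118, and adjusted p = 0.03 with an estimated correlation). Egr1 rose by 2.73 ± 0.16, Junb by 2.39 ± 0.20, Klf6 by 1.47 ± 0.10 and Klf4 by 1.27 ± 0.12. With anti-PD1 8 rose and 2 fell (9 and 3 over the list alone), with a median of 1.47 (adjusted p = 3.54e-05, and adjusted p = 0.0244 with an estimated correlation). With TNF + IFNG 3 members rose (5 up and 1 down over the list alone), and the list did not pass (adjusted p = 0.283). Among them, Jun rose by 0.89 ± 0.12, a call lost without the first untreated library (adjusted p = 0.0627). Of 13 p53 targets in isotype co-culture, 4 rose and 2 fell, and the list did not pass (adjusted p = 0.13). Btg2 (2.65 ± 0.37, 1 of 3 controls at the detection floor), the cell cycle inhibitor gene Cdkn1a (1.04 ± 0.14) and Mdm2 (1.03 ± 0.16), which encodes a ligase that marks p53 for degradation, rose. Trp53inp1, which promotes cell death, fell by 2.06 ± 0.45, a call lost without the third isotype library (adjusted p = 0.0566). Of 15 genes of the unfolded protein and integrated stress responses, 3 rose with isotype (adjusted p = 0.0452, and adjusted p = 0.245 with an estimated correlation) and 5 with anti-PD1 (adjusted p = 0.007, and adjusted p = 0.142 with an estimated correlation), Atf4 by 0.65 ± 0.13 and 0.60 ± 0.13. The isotype call of that list was lost without the first library of MC38 alone (adjusted p = 0.0874), without the third (0.105), and without the first or second isotype library (0.0563 and 0.066).

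Mitochondrially encoded genes fell in co-culture with isotype, 11 of 30 members with a median of −0.37 (camera adjusted p = 0.00274, and adjusted p = 0.0242 with an estimated correlation), among them mt-Nd2 (−1.59 ± 0.31) and mt-Co2 (−1.44 ± 0.28). With anti-PD1 7 fell (10 over the list alone), with a median of −0.38 (adjusted p = 0.0111, and adjusted p = 0.0455 with an estimated correlation). This list also lay lower in vitro, so the direction is not particular to co-culture. Its medians were −0.31 with supernatant, −0.20 with TNF and −0.12 with TNF + IFNG (camera adjusted p = 0.000127, 0.00425 and 0.024). With an estimated correlation these did not pass (adjusted p = 0.163, 0.299 and 0.439). With IFNG the list did not pass (camera adjusted p = 0.0661). Of 76 ribosomal protein genes, 13 fell with isotype and 16 with anti-PD1, with medians of −0.16 and −0.14 (adjusted p = 0.000881 and 0.00137, and adjusted p = 0.207 and 0.21 with an estimated correlation); Rps12 fell by 0.68 ± 0.10 and 0.71 ± 0.10. Of 17 genes of cholesterol synthesis, Insig1 fell by 1.37 ± 0.26 and Stard4 by 0.64 ± 0.11 with isotype, where 3 fell and 1 rose (list adjusted p = 0.0337, and adjusted p = 0.0821 with an estimated correlation). That list call was lost without the first or second library of MC38 alone (adjusted p = 0.0877 and 0.0571). With TNF + IFNG 2 of these fell and 1 rose (list adjusted p = 0.00565, and adjusted p = 0.0633 with an estimated correlation). Of 27 cell cycle genes, 5 fell and 1 rose with anti-PD1 (list adjusted p = 0.00791, and adjusted p = 0.116 with an estimated correlation), Mki67 by 1.17 ± 0.23, and the list call was lost without the third library of MC38 alone (adjusted p = 0.102). With isotype 1 fell and 1 rose, with a median of −0.17 (camera adjusted p = 0.0202, and adjusted p = 0.174 with an estimated correlation). Of 11 marker genes of the tumour line, 1 passed in either co-culture, Fn1 (−0.95 ± 0.27 with isotype and −1.18 ± 0.27 with anti-PD1), and the list did not (adjusted p = 0.455 and 0.41). The isotype call of Fn1 was lost without any 1 of 6 libraries (adjusted p up to 0.134), and the anti-PD1 call without the third anti-PD1 library (0.0545). The co-culture libraries hold RNA of T cells as well, so these values are not of tumour cells alone.

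T cell marker transcripts, but not effector transcripts, stood at co-culture levels in the third library of MC38 alone, the shallowest of that table. Low depth is argued against, because the T cell markers lay at a median step of 11 among the distinct values of that library, above the lowest 3. RNA of a co-culture library or a swapped label is argued against as well: effector genes reached a median of 38.7% of their co-culture level and markers 108% (permutation p = 0.0011). Summed, the effector genes stood at 69.2 CPM there, against 328 to 405 in the co-cultures. The permutation shuffled genes of 1 library, which vary together, so its p does not measure the spread between libraries. RNA of T cells that had not met tumour cells cannot be told apart from other sources, since resting T cell genes lay at a median of −0.59 against co-culture, 5 of 9 were tested, and only 1 was on the lowest 3 steps in both other controls. Libraries of OT1 T cells alone were not analysed here, and no biological explanation was tested.

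More genes passed with TNF + IFNG (1147) than with TNF (35) or IFNG (45). With only the compared groups fitted, the count with TNF + IFNG was 0.302 times that with IFNG (145 against 480), but still above that with TNF (61). Unequal spread between the groups can account for the excess over IFNG, and was not shown to account for that over TNF. The median SD between replicates was 0.262 with TNF + IFNG, 0.161 with TNF and 0.118 with IFNG. Low depth of the second TNF + IFNG library is argued against as the whole cause, since 307 genes passed without it. Of the genes called with TNF + IFNG 3.62% were pseudogenes, against 9.28% of those tested (Fisher's exact p = 2.11e-14). The share was also below that of the tested genes with TNF (0%) and IFNG (2.22%), and was not lower with TNF + IFNG than with these. The test therefore cannot decide whether reads shared with pseudogenes add to the count. How far the cytokines together change more genes than either alone therefore stays open.

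Supernatant raised interferon genes and few NF-kB targets. A stimulus weaker for both gene groups alike is argued against: the median difference from TNF + IFNG was 0.0163 for 47 interferon genes and −1.11 for 26 NF-kB targets. Permuting genes between the 2 groups gave p = 1e-05, the smallest the permutations can give. Genes are not independent replicates, so this p does not measure the spread between libraries. No doses were compared, so a weaker stimulus that still raised interferon genes to their limit cannot be told apart. T cell RNA as the carrier of NF-kB transcripts in co-culture cannot be told apart from expression in tumour cells: in the third library of MC38 alone, which holds T cell RNA, the 26 targets differed from the other controls by a median of −0.0336 (1.99 in co-culture), but its T cells hold fewer effector transcripts than those in co-culture. Little TNF activity in the supernatant cannot be told apart from other causes: the 28 genes called with TNF and not with IFNG had a median change of 0.30 with supernatant and 1.88 with TNF, and TNF itself was not measured there. Contact with T cells, which differs between supernatant and co-culture, was not tested as a biological explanation. Neither was the time with supernatant, which is not recorded.

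Each comparison of co-culture groups has 10 splits of its 6 libraries, too few splits for a share under 0.05. For isotype against MC38 alone, 1 split, the real one, gave as many genes (1761, with 1 the highest other), and for anti-PD1 against MC38 alone also 1 (2050, with 1 the highest other). For anti-PD1 against isotype all 10 splits gave at least the real count of 0, and the highest other was 3.

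Supernatant against IFNG gave 1 gene, Slc30a1, which rose and is outside the naming rule, and supernatant against TNF gave 82, 54 up and 28 down. Of 525 genes called with TNF + IFNG and with neither single cytokine, 170 rose in isotype co-culture and 9 with supernatant. Over all 12165 genes tested in both tables, 876 rose in isotype co-culture. The median log2 fold of the 525 genes was 0.37 with TNF, 0.43 with IFNG and 0.99 with both. The 2 genes that passed the interaction test, Cxcl9 and Irf1, are not among them, so these genes are not shown to need both cytokines. Il2, a gene of T cells, rose by 2.56 ± 0.36 with TNF + IFNG in libraries to which no T cells were added (adjusted p = 0.00967), a call lost without the first untreated library (adjusted p = 0.0627) or the second (0.0726). Of 542 genes tested in co-culture under a name not tested in vitro, 95 rose and 10 fell with isotype, against 971 and 790 of all 12707 genes. Some of the 542 may be in the in vitro table under another name, since 15 names there had been turned into dates.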
